A study of Homo sapiens with 18 samples.

How the data were processed

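The series holds RNA sequencing of 18 libraries in 6 groups of 3, all from a commercial human episomal induced pluripotent stem cell line and its neural derivatives. Per the labels, libraries were made from 1 microgram of total RNA and read as 76 bp single reads, and the labels name both an unstranded and a stranded mRNA kit, so the kit is uncertain. The submitters' processing notes name STAR 2.5.3a, HTSeq, edgeR and GRCh38 without their order or settings, and the annotation release is not given in the sources used here. The deposited values are log2 normalized CPM for 14619 genes, 13974 with a symbol, as the authors made them.

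The unit was checked on the values. All 18 columns share 1 floor of -3.27, or 0.104 CPM, and once the floor is taken off every library steps in whole reads (100% of values under 20000 reads within 0.05 of a whole number). This gave effective library sizes from 9.19 to 42.3 M reads and reads in the listed genes from 9.79 to 41.01 M, with a median of 20.1 M. Between 126 and 299 genes per library sat at the floor. Read numbers in the text are these recovered reads. A fold against a group with no reads is given as at least the value that 3 reads over that group would allow, and no fold is given where 1 to 3 reads remain. Such floors cover counting error only. Replicates varied more than counting alone gives, with chi-square values per degree of freedom between 1.97 and 268 for pairs of libraries. The pairs with idebenone library 1 had 208 and 268, and all others at most 19.3.

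Groups, comparisons, gene lists, fixed genes, tests and a first set of other settings were written down before the data were examined. All 18 libraries were fitted with group means in limma 3.58.1 under R 4.3.3, with moderated variances and a trend on mean expression, two-sided tests and Benjamini-Hochberg adjustment at 0.05 within each of 7 comparisons. The fit has 12 residual and 2.95 prior degrees of freedom. A filter of log2 CPM above 0 in at least 3 libraries removed no gene, since every gene already met it, so a run without a filter is void. Of 50 fixed gene lists with 1007 entries, 862 entries were measured, and 46 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01 and again with an estimated one. Counts adjusted over the list alone use only the members of that list.

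The text names genes by this rule. In each comparison it takes, among passing genes with the same sign in all 3 same-numbered differences, a higher group mean of at least log2 CPM 4 and a protein-coding symbol, the 12 with the largest rise and the 12 with the largest fall. Where fewer than 24 genes passed, the 6 with the largest moderated t on each side are given as values. Added to these are up to 4 members of each called list with the smallest p, and 38 genes fixed in advance, 34 of them measured. The few genes outside the rule are marked as chosen after their values were seen.

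The other settings in that first set were log2(CPM + 1) and log2(CPM + 5), a filter at log2 CPM above 2 that leaves 13310 genes, median scaling, quantile normalization, no variance trend, robust variances, limma library weights, a fit of only the 2 groups compared, each library left out in turn, and the replicate number as a block. The labels say that the numbers mark independent differentiation experiments, which is where the pairing comes from. Same-numbered libraries deviated from their group means with a mean correlation of 0.0769 over 45 pairs, and others with -0.038 over 90 pairs. Deviations cancel out within a group, so the second value largely follows from the first and is no separate evidence. Chosen after seeing the data were leaving out idebenone library 1, voom on recovered reads, and removing trends with transcript length and GC content. These trends were splines with 4 degrees of freedom fitted in each library to 10551 genes with log2 CPM above 3, with lengths and GC from GENCODE release 29 for 14592 genes (99.8%). They were fitted to deviations from the mean of all libraries in the fit, so a stage difference that follows length or GC is removed as well. Without idebenone library 1 the fit has 11 residual and 7.09 prior degrees of freedom.

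The overlap of the drug effects was compared with 100 simulations of unchanged groups that share 3 controls. The tests were also run on simulated libraries with planted changes. Their counts were drawn with the same assumed dispersion for every gene, and the same changes were planted for both drugs, only in genes expressed in NP. Idebenone library 1 was given its real deviations up to a cap, and the other libraries none beyond that dispersion. The recovered shares therefore hold for such libraries and may differ for the real ones. In idebenone against NP 47.8% of genes shifted by log2 1 were recovered and 92.4% of those shifted by 2, and 8.96% of those shifted by 0.5. Leaving out idebenone library 1 gave 88.1, 100 and 31.3%. In bezafibrate against NP the same sizes gave 47.8, 97.0 and 4.48%, or 94.0, 100 and 52.2%. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.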

Results

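RNA was sequenced from 18 cultures derived from a commercial human episomal induced pluripotent stem cell line. The cultures fell into 6 groups of 3 libraries each: the pluripotent cells (hiPSC), neural stem cells made from them (NSC), early neural progenitors (eNP), neural progenitors (NP), and neural progenitors kept for 5 days with either 0.5 microM idebenone, a quinone related to coenzyme Q, or 50 nM bezafibrate, a fibrate that activates the PPAR receptors. Per the labels, the 3 libraries of a group came from 3 independent differentiation experiments. The values were log2 normalized CPM for 14619 genes. Reads in these genes came to 28.1, 13.7 and 20.1 M (megareads) in hiPSC, 12.7, 17.8 and 10.9 M in NSC, and 18.01, 16.99 and 41.01 M in eNP. The NP libraries held 25.3, 19.8 and 21.7 M reads, the idebenone libraries 9.79, 21.4 and 26.6 M, and the bezafibrate libraries 23.9, 23.0 and 20.1 M. All listed genes with a mitochondrial genome symbol took between 2.35 and 2.59% of the reads in hiPSC and between 5.15 and 5.67% in NP.

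The first principal component held 73.9% of the variance between libraries and the second 15.98%. Idebenone library 1 stood apart from the other 8 neural progenitor libraries: its deviations from their mean had an SD over genes of 1.06 on the log2 scale. Measured against the mean of the other 8, its ribosomal protein genes had a median of 1.82, its complex I genes 1.78, and its extracellular matrix genes -1.40. All 18 libraries stayed in the tests. Leaving this library out moves no fold change between the other groups, only the spread that the tests use and so which genes and lists pass. In what follows a change is a log2 fold change with its standard error, a level is a mean log2 CPM with its SD, each group has 3 libraries, a value given for a gene or a list is a change unless called a level, and an adjusted p is two-sided from limma for a gene and from camera for a gene list.

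**Figure D1:**
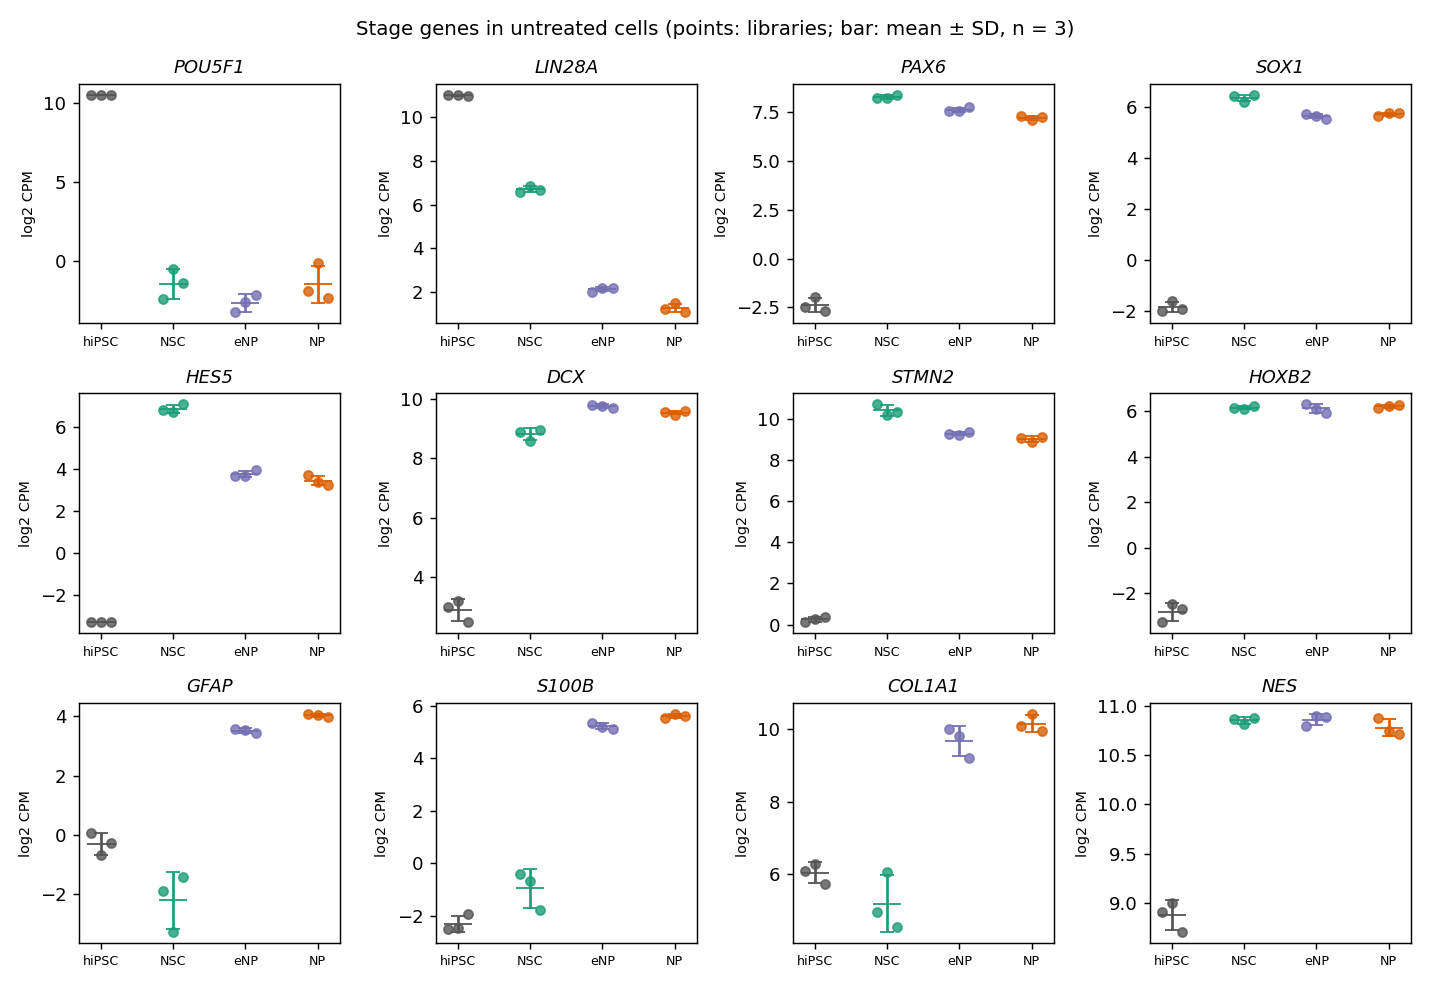
Log2 CPM of 12 stage marker genes (vertical axes) in the 4 untreated groups hiPSC, NSC, eNP and NP (horizontal axes), with a point for each library and a bar for the mean ± SD (n = 3). POU5F1 lay at 10.50 in hiPSC and -1.46 in NSC, PAX6 at -2.39 and 8.29, and GFAP rose from -2.19 in NSC to 3.52 in eNP.

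The step from hiPSC to NSC asked which genes changed when pluripotent cells became neural stem cells. The pluripotency regulator POU5F1 fell from 10.50 ± 0.03 in hiPSC to -1.46 ± 0.94 in NSC, a change of -11.96 ± 0.84 (adjusted p = 3.31e-09), with 14 reads left over the 3 NSC libraries. The neural transcription factors PAX6 and SOX1 rose by 10.68 ± 0.17 (adjusted p = 2.32e-16) and 8.22 ± 0.11 (adjusted p = 5.75e-17). STMN2, a microtubule regulator of young neurons, rose by 10.14 ± 0.12 (adjusted p = 2.96e-17), and NR2F1, a nuclear receptor of the developing nervous system, by 10.46 ± 0.23. The adhesion molecule of epithelia CDH1 fell by 9.23 ± 0.21, and its level was lower in all 3 NSC libraries.

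All 24 measured members of the pluripotency list fell (camera adjusted p = 5.67e-11), and the median over members went from 7.75 ± 0.07 to -1.06 ± 0.45. L1TD1, an RNA-binding protein of pluripotent cells, changed by -12.08 ± 0.92, the RNA-binding protein LIN28A by -4.31 ± 0.26 and the DNA methyltransferase DNMT3B by -4.74 ± 0.18. NANOG had a level of 5.36 in hiPSC and 1 read over the NSC libraries. POU5F1 and NANOG have pseudogenes close in sequence, so how their reads were assigned is uncertain. All 10 members of the epithelium list fell as well (camera adjusted p = 3.22e-06), with a median level of 7.49 ± 0.09 in hiPSC and -1.15 ± 0.75 in NSC. The adhesion molecule EPCAM changed by -8.51 ± 0.40 and the keratin KRT19 by -8.39 ± 0.40, while GRHL2, a transcription factor of epithelia, had no reads in NSC and was at least 532-fold lower.

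Of the 22 neural stem genes, 17 rose, 1 fell and 4 did not pass (camera adjusted p = 4.64e-07), and adjusted over the list alone 18 rose and 2 fell. HES5, a target of Notch signaling, had no reads in hiPSC and 4581 in NSC, a rise of at least 2282-fold. The intermediate filament genes VIM and NES rose by 5.05 ± 0.15 and 1.98 ± 0.12, and the fatty acid binding protein gene FABP7 by 3.16 ± 0.21. SOX2, expressed in pluripotent and neural stem cells alike, had a change of 0.49 that did not pass (adjusted p = 0.0619). All 12 proneural genes rose (camera adjusted p = 1.7e-07), among them the transcription factors INSM1 by 6.38 ± 0.18 and NHLH1 by 7.12 ± 0.16, and NEUROG2, without reads in hiPSC, by at least 146-fold. Their median level in hiPSC was -1.12 ± 0.40. Genes silent there are listed only if other libraries expressed them, so this rise was in part set in advance. In the neuron list 21 of 27 members rose and 4 fell (camera adjusted p = 4.27e-06, and adjusted p = 0.0986 with an estimated correlation). Its median change was 3.27, and examples are the microtubule proteins DCX at 5.93 ± 0.22 and MAP2 at 4.36 ± 0.28, the neurofilament gene NEFL at 4.83 ± 0.08 and the RNA-binding protein gene ELAVL3 at 7.03. Of the 17 Notch pathway genes 14 rose and 2 fell (camera adjusted p = 0.00346), with the ligand DLL1 at 5.72 ± 0.22 and the hairy-related repressors HES4 at 7.23 ± 0.39 and HEY2 at -6.47 ± 0.36.

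All 10 measured of 29 fixed HOX genes, which pattern the hindbrain and spinal cord, rose (camera adjusted p = 1.23e-07), and their median level went from the floor of -3.27 in hiPSC to 3.04 ± 0.14 in NSC. The values hold only genes above log2 CPM 0 in at least 3 libraries. A HOX gene silent in hiPSC is thus among them only if other libraries expressed it, so that rise was in part set in advance. HOXA2 had a level of 6.06 in NSC and HOXB2 one of 6.16, each with 2 reads over the hiPSC libraries, and HOXB8 was at least 152-fold higher. In the midbrain and hindbrain list 6 of 7 members rose (camera adjusted p = 0.00637), with the homeobox genes IRX3 at 6.13 ± 0.15 and GBX2 at 6.24 ± 0.34. Among the 6 dorsal genes 5 rose (camera adjusted p = 0.00388), including PAX7 by 8.15 ± 0.29 and the zinc finger gene ZIC1 by 6.61 ± 0.17. OTX2, a homeobox gene of the forebrain and midbrain, went from a level of 5.59 to -2.63, the latter from 3 reads.

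Glycolysis genes were lower in NSC: 15 of 19 fell and 2 rose, with a median of -0.83 (camera adjusted p = 0.000558, and adjusted p = 0.107 with an estimated correlation). The lactate dehydrogenase gene LDHA changed by -3.27 ± 0.09, the hexokinase gene HK1 by -2.00 ± 0.09 and the glucose transporter gene SLC2A3 by -2.80 ± 0.15. In the lipogenesis list 8 of 10 genes fell and 2 rose (median -0.998, camera adjusted p = 0.0464, and adjusted p = 0.489 with an estimated correlation). Malic enzyme ME1 stood at -3.05 ± 0.16. Of the 17 NRF2 target genes 13 fell and 1 rose (median -1.01, camera adjusted p = 0.0112, and adjusted p = 0.107 with an estimated correlation). The heme oxygenase gene HMOX1 stood at -3.16 ± 0.20. The p53 target list had 14 of 17 genes up and none down, or 1 down adjusted over the list alone (median 1.87, camera adjusted p = 4.58e-05), led by the cell cycle inhibitor CDKN1A at 4.83 ± 0.15. Among 25 genes of the G1/S phase 17 fell and 3 rose (median -0.87, camera adjusted p = 0.00612), or 4 rose adjusted over the list alone, with the cyclin gene CCNE1 at -2.80 ± 0.10 and the replication licensing gene MCM3 at -2.39 ± 0.09. Ribosomal protein genes had 40 of 75 members up and 2 down (median 0.86, camera adjusted p = 0.00583, and adjusted p = 0.813 with an estimated correlation). RPL5 stood at 1.26 ± 0.20. With idebenone library 1 left out 65 of these genes rose and 3 fell (camera adjusted p = 2.88e-06, and adjusted p = 0.561 with an estimated correlation). The mitochondrial regulator PPARGC1A rose by 2.11 ± 0.26 (adjusted p = 2.25e-06), PPARGC1B changed by -3.27 ± 0.16, and TFAM, which packages and transcribes mitochondrial DNA, by -0.82 ± 0.19 (adjusted p = 0.00119).

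In this step 10211 genes passed at an adjusted p under 0.05, 5145 up and 5066 down, and 15 of 46 gene lists were called. With length and GC trends removed 4891 genes were up and 6548 down, so the near-even split does not hold in that fit. The lipogenesis call ended without idebenone library 1 (adjusted p = 0.0518) and with length and GC trends removed (adjusted p = 0.0573), while its median was -0.998 and -1.126 in these fits. Over all alternatives of that kind its adjusted p ran from 0.0452 to 0.0688. The fit without that library also called the mitochondrial ribosome list (median -0.28, adjusted p = 0.0343, and adjusted p = 0.707 with an estimated correlation) and the G2/M list (median -0.49, adjusted p = 0.0426, and adjusted p = 0.462 with an estimated correlation). With trends removed and all libraries kept the G2/M list was called too (median -0.64, adjusted p = 0.0332, range 0.0135 to 0.0832), as was the neural crest list (median 3.996, from 4.09, adjusted p = 0.0425, range 0.0425 to 0.127). With an estimated correlation and idebenone library 1 left out, only the pluripotency, neural stem and HOX lists kept their calls, with adjusted p = 0.0203, 0.0125 and 0.0125.

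The step from NSC to eNP asked what changed as neural stem cells became early progenitors. S100B, a calcium-binding protein of astrocytes, rose by 6.19 ± 0.36 (adjusted p = 3.39e-09), and the intermediate filament gene GFAP by 5.71 ± 0.35 (adjusted p = 4.67e-09), from 5 to 872 reads. The transcription factor NFIX rose by 8.40 ± 0.48 (adjusted p = 2.91e-09), and the matrix genes TGFBI and FBLN5 by 7.82 ± 0.25 and 6.82 ± 0.16. LIN28A changed by a further -4.59 ± 0.26 (adjusted p = 2.64e-09) and HES5 by -3.09 ± 0.36 (adjusted p = 3.80e-06). Of 75 ribosomal protein genes 70 fell, with a list median of -1.62 (camera adjusted p = 1.79e-18, and adjusted p = 0.5 with an estimated correlation).

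Of the 11 astrocyte genes 6 rose and 1 fell (median 0.90, mean 2.16, camera adjusted p = 0.0187, and adjusted p = 0.124 with an estimated correlation). The astrocyte call ended without idebenone library 1 (adjusted p = 0.0564), with the median unmoved. CD44, the hyaluronan receptor, rose by 4.19 ± 0.26 and SPARCL1, a matrix protein made by astrocytes, by 3.56 ± 0.25. In the neuron list 20 of 27 genes rose and 3 fell (median 0.64, camera adjusted p = 0.0104, and adjusted p = 0.5 with an estimated correlation). MAP2 stood at 1.44 ± 0.28, DCX at 0.96 ± 0.22, the adhesion molecule NCAM1 at 1.16 ± 0.12 and STMN2 at -1.13 ± 0.12. Of 5 genes of GABA neurons 4 rose (median 3.27, camera adjusted p = 0.00292, and adjusted p = 0.0633 with an estimated correlation). The homeobox gene DLX1 stood at 4.36 ± 0.21 and GAD1, which makes GABA, at 1.85 ± 0.20. The median level of this list in NSC was -0.96, and genes that low are listed only if other libraries expressed them. Of 8 genes of glutamate neurons 7 rose (camera adjusted p = 0.00243, and adjusted p = 0.294 with an estimated correlation). The glutamate transporter gene SLC17A6 stood at 2.27 ± 0.27 and the transcription factor BCL11B at 3.99 ± 0.27. Their median level went from 0.47 ± 0.24 to 2.44 ± 0.15. The synapse list had 19 of 30 genes up and 2 down (median 0.55, camera adjusted p = 0.0131, and adjusted p = 0.545 with an estimated correlation), or 3 down adjusted over the list alone. In it the adhesion molecule NLGN3 rose by 2.47 ± 0.12 and the glutamate receptor gene GRIA1 by 2.27 ± 0.21.

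Mesenchyme genes rose in 10 of 13 cases (median 1.83, camera adjusted p = 0.000555, and adjusted p = 0.342 with an estimated correlation). The collagen genes changed as well: COL1A1 stood at 4.47 ± 0.31 (adjusted p = 1.65e-08) and COL1A2 at 2.75 ± 0.23. In the extracellular matrix list 17 of 23 genes rose and 2 fell (median 1.54, camera adjusted p = 0.000234, and adjusted p = 0.513 with an estimated correlation), or 18 up adjusted over the list alone. The laminin genes LAMA2 and LAMA4 rose by 4.35 ± 0.31 and 2.92 ± 0.11. Of 17 interferon response genes 11 rose and none fell (median 1.72, camera adjusted p = 0.000813, and adjusted p = 0.0741 with an estimated correlation). IFIT2 stood at 4.17 ± 0.30 and IFI44 at 3.46 ± 0.16. Cholesterol synthesis genes had 13 of 25 members up and 1 down (median 0.47, camera adjusted p = 0.0131, and adjusted p = 0.128 with an estimated correlation). CPT1A, the carnitine acyltransferase that admits fatty acids to mitochondria, rose by 3.28 ± 0.11 (adjusted p = 9.24e-12), and PPARGC1A by 2.23 ± 0.26.

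The 25 G1/S genes had 15 members down and none up (median -0.56, camera adjusted p = 1.79e-05), with the proliferating cell antigen PCNA at -1.20 ± 0.11 and the ribonucleotide reductase gene RRM1 at -1.13 ± 0.09. Of the 27 G2/M genes 21 fell, or 22 adjusted over the list alone (median -0.61, camera adjusted p = 6.18e-08, and adjusted p = 0.0633 with an estimated correlation). The mitotic kinase CDK1 stood at -1.52 ± 0.14 and UBE2C at -1.28 ± 0.10. The p53 targets had 11 of 17 members down and 3 up (median -0.81, camera adjusted p = 0.0043, and adjusted p = 0.0633 with an estimated correlation), or 4 up adjusted over the list alone, with AEN at -1.30 ± 0.11. Of the 24 pluripotency genes 8 fell further and 1 rose (camera adjusted p = 0.00548, and adjusted p = 0.264 with an estimated correlation). SALL4 stood at -1.89 ± 0.09, and the median level of the list went from -1.06 ± 0.45 to -2.36 ± 0.11. The 10 HOX genes had 4 members down and 1 up (median -0.18, camera adjusted p = 0.0451, and adjusted p = 0.18 with an estimated correlation). HOXB8 stood at -2.42 ± 0.13. Their call ended with the replicate number as a block (adjusted p = 0.0615) and without idebenone library 1 (adjusted p = 0.175).

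Nuclear genes of the respiratory chain and genes of both ribosomes were lower in eNP, and the ribosomal protein genes among them have many pseudogenes that can share their reads. Ribosomal protein genes had a median change of -1.62 (camera adjusted p = 1.79e-18, and adjusted p = 0.5 with an estimated correlation). RPS23 stood at -2.00 ± 0.18 and RPLP0 at -1.53 ± 0.15. Of 74 genes of the mitochondrial ribosome 43 fell and none rose (median -0.83, camera adjusted p = 2.12e-09, and adjusted p = 0.513 with an estimated correlation), or 46 down and 1 up adjusted over the list alone, with MRPL30 at -1.46 ± 0.11. In complex I 13 of 35 genes fell and 1 rose (median -0.64, camera adjusted p = 0.00243, and adjusted p = 0.608 with an estimated correlation), or 12 down adjusted over the list alone, with NDUFS4 at -1.61 ± 0.25. With idebenone library 1 left out 27 complex I genes fell and 4 rose. Complexes II and III had 5 of 13 genes down, or 4 adjusted over the list alone (median -0.60, camera adjusted p = 0.0131, and adjusted p = 0.545 with an estimated correlation). UQCRC2 stood at -0.86 ± 0.09, and 10 genes of these complexes fell and 1 rose once idebenone library 1 was left out. In complex IV 8 of 13 genes fell (median -0.97, camera adjusted p = 0.002, and adjusted p = 0.545 with an estimated correlation). COX7C stood at -1.71 ± 0.32. The ATP synthase had 11 of 16 genes down, or 12 adjusted over the list alone (median -0.87, camera adjusted p = 0.000423, and adjusted p = 0.545 with an estimated correlation). ATP5C1 stood at -1.18 ± 0.15. TFAM changed by -0.78. The 13 protein genes of the mitochondrial genome went the other way: 5 rose and none fell, or 1 up adjusted over the list alone, with a median of 0.52 that was not called (camera adjusted p = 0.308). Leaving out idebenone library 1, 10 of them rose, and with length and GC trends removed the list was called at a median of 1.14 (adjusted p = 0.0116). Over the fits with the block, the trends removed or that library left out, its adjusted p ran from 0.00035 to 0.308.

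In this step 7420 genes passed, 4308 up and 3112 down, and 20 lists were called. Under quantile normalization, which moved the median of all genes by -0.133, the share of changed genes that were higher went from 58.1% to 47.5%, so the balance of directions turned, while no called list changed the sign of its median. With length and GC trends removed that share was 48.4%. With length and GC trends removed 6 calls ended, but that removal also takes out any stage difference that follows length or GC. Complex I then had a median of -0.36 (adjusted p = 0.108), complexes II and III -0.47 (adjusted p = 0.12), complex IV -0.54 (adjusted p = 0.209) and synapse genes 0.27 (adjusted p = 0.117), all nearer 0 than before. Astrocyte genes at 1.13 (adjusted p = 0.0548) and HOX genes at -0.33 (adjusted p = 0.14) were farther from 0. When idebenone library 1 was left out as well, complexes I and IV passed (adjusted p = 0.0405 and 0.0358) and the pluripotency call ended (median -0.52, adjusted p = 0.0923). Over the fits with the block, the trends removed or that library left out, the adjusted p ran from 1.78e-05 to 0.108 for complex I, 0.0019 to 0.12 for complexes II and III, 8.73e-06 to 0.209 for complex IV, 0.00541 to 0.117 for synapse, 0.0187 to 0.0898 for astrocyte, 0.0451 to 0.279 for HOX and 0.00548 to 0.0923 for pluripotency genes.

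**Figure D2:**
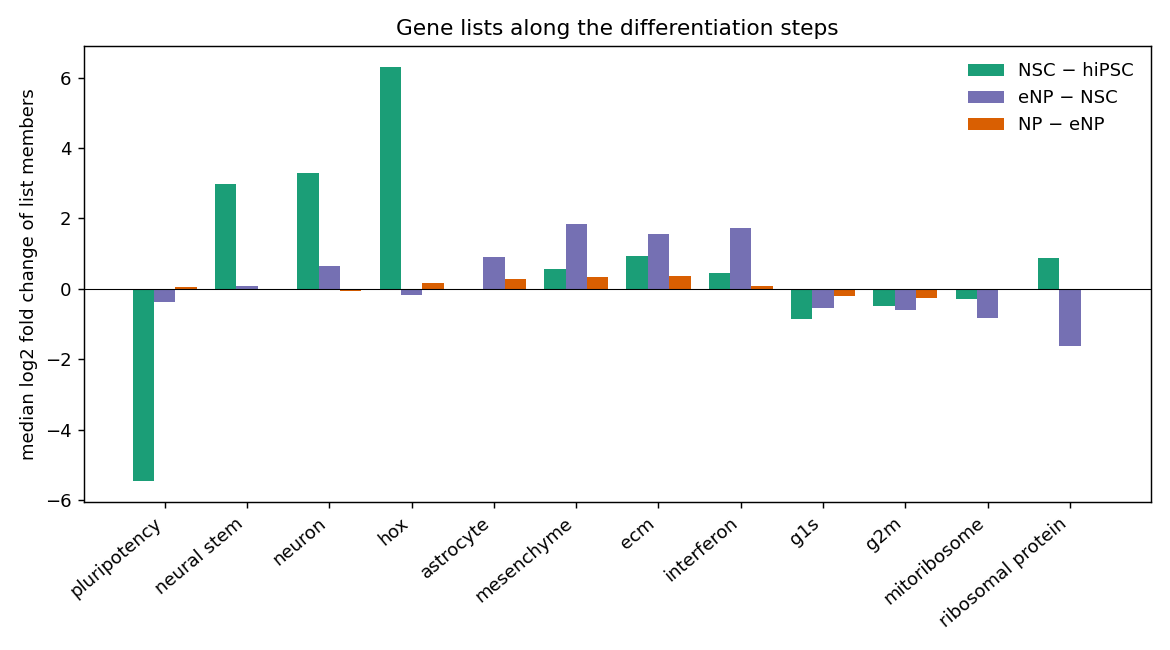
Median log2 fold change (vertical axis) over the measured members of 12 gene lists in the steps NSC minus hiPSC, eNP minus NSC and NP minus eNP, each bar a median over genes from groups of 3 libraries. Ribosomal protein genes went from 0.86 in the first step to -1.62 in the second, with the same signs under median scaling and quantile normalization, and no bar for the NP minus eNP step of a called list exceeded 0.37.

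The step from eNP to NP asked what changed between the last stages. Differences were small, and 1 gene passed: MIR217HG, a long noncoding RNA, fell by 1.54 ± 0.21 (adjusted p = 0.0404). Its level in eNP, the higher group, was only -0.49, so the call rests on a weakly expressed gene. MIR217HG lies outside the rule for named genes and was chosen after its values were seen. The test gave an unadjusted p under 0.05 for 1045 genes, and voom, the read-based form of limma, passed 0 genes with 1338 unadjusted. If nothing changed, a share of about 0.05 of the 14619 genes would have such a p. With the replicate number as a block the count was 0. The count without idebenone library 1 was 1087, 538 up and 549 down.

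Among the largest moderated t values were those of SALL4, a zinc finger gene of early development, at -0.60 ± 0.09 (adjusted p = 0.062), the matrix protease MMP2 at 0.53 ± 0.10 (adjusted p = 0.189) and the matrix proteoglycan AGRN at 0.60 ± 0.12 (adjusted p = 0.189). With idebenone library 1 left out these had adjusted p = 0.00058, 0.0029 and 0.0040. Over 10551 genes the changes of this step had a rank correlation (Spearman) of 0.514 with GC content. The GC content is 67.5% for AGRN, 56.5% for MMP2 and 51.3% for SALL4. The changes of these genes with that trend removed are not given here. Cell cycle lists were lower and matrix lists higher in NP. The G1/S list had a median of -0.21 (camera adjusted p = 4.77e-09), with 0 members down over all genes and 2 adjusted over the list alone, and RRM1 at -0.32 ± 0.09. The G2/M list had a median of -0.25 (camera adjusted p = 1.78e-08, and adjusted p = 0.0507 with an estimated correlation), with 1 member down adjusted over the list alone and CCNB2 at -0.34 ± 0.08. Leaving out idebenone library 1, 10 G1/S and 15 G2/M genes fell over all genes, and 16 and 17 adjusted over the list alone.

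The extracellular matrix list had a median of 0.37 (camera adjusted p = 2.62e-06, and adjusted p = 0.828 with an estimated correlation), with 2 of 23 members up adjusted over the list alone and LAMA5 at 0.65 ± 0.14. Once idebenone library 1 was left out, 9 of its members rose and 1 fell. The mesenchyme list had a median of 0.32 (camera adjusted p = 0.00223, and adjusted p = 0.828 with an estimated correlation). COL5A1 stood at 0.55. The BMP and TGF-beta target list stood at 0.30 (camera adjusted p = 0.00223, and adjusted p = 0.0881 with an estimated correlation). ID1 stood at 0.78. The immediate early list stood at 0.24 (camera adjusted p = 0.0376, and adjusted p = 0.951 with an estimated correlation), with 2 members up adjusted over the list alone and JUNB at 0.72. In total 6 lists were called, and the immediate early call ended without idebenone library 1 (adjusted p = 0.104) and with length and GC trends removed (median 0.19, adjusted p = 0.209), within a range over such alternatives of 0.0126 to 0.266. In the fit without that library the G1/S list had adjusted p = 0.0555 and the G2/M list adjusted p = 0.039 with an estimated correlation. That fit also called complex I (median 0.08, adjusted p = 0.0427, and adjusted p = 0.958 with an estimated correlation). With trends removed as well, complex IV was called too (median 0.19, camera adjusted p = 0.00301). With all libraries and no trend removed its median was 0.13, not called (camera adjusted p = 0.746).

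The comparison of NP with hiPSC spanned the whole differentiation. A2M, a protease inhibitor, rose from 1.12 to 12.86, a change of 11.74 ± 0.36 (adjusted p = 1.37e-13), the collagen gene COL3A1 by 11.19 ± 0.31 and NTRK2, the receptor of the growth factor BDNF, by 10.89 ± 0.27. PAX6 and SOX1 were 9.61 ± 0.17 and 7.58 ± 0.11 higher in NP, and FABP7 6.53 ± 0.21 higher. POU5F1 changed by -11.99 ± 0.84 (adjusted p = 2.59e-09) and LIN28A by -9.76 ± 0.26. ZFP42, a zinc finger gene of pluripotent cells, had no reads in NP and was at least 7507-fold lower.

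All 24 pluripotency genes fell (camera adjusted p = 7.14e-12) and all 10 epithelium genes (camera adjusted p = 6.8e-06), with EPCAM at -9.85 ± 0.40. In the neural stem list 20 of 22 genes rose (median 3.87, camera adjusted p = 3.49e-07), with SOX2 at 0.65 ± 0.22 (adjusted p = 0.0151). All 12 proneural genes rose (camera adjusted p = 1.18e-06). The neuron list had 24 of 27 genes up and 3 down (median 3.63, camera adjusted p = 9.58e-07, and adjusted p = 0.0669 with an estimated correlation). STMN2 stood at 8.74 ± 0.12 and NEFL at 5.46 ± 0.08. All 5 measured of 10 fixed GABA neuron genes rose (camera adjusted p = 0.00723), with GAD1 at 3.86 ± 0.20. In hiPSC the median level was -1.12 for the proneural and -2.03 for the GABA neuron list. Genes silent in hiPSC are listed only if other libraries expressed them, so the rises of these lists were in part set in advance. Of 8 glutamate neuron genes 7 rose (camera adjusted p = 0.00335, and adjusted p = 0.224 with an estimated correlation), and the receptor gene GRIA2, without reads in hiPSC, was at least 529-fold higher. The synapse list had 23 of 30 genes up and 6 down (median 1.46, camera adjusted p = 0.00312, and adjusted p = 0.343 with an estimated correlation). GRIA1 stood at 7.71 ± 0.21. The Notch list had 14 of 17 genes up and 1 down (median 1.85, camera adjusted p = 0.00264), with DLL1 at 5.52.

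All 10 HOX genes rose (camera adjusted p = 1.79e-06) and all 7 midbrain and hindbrain genes (camera adjusted p = 0.00194), while 5 dorsal genes rose and 1 fell (camera adjusted p = 0.0173, and adjusted p = 0.0855 with an estimated correlation). Genes silent in hiPSC are again listed only if other libraries expressed them, so such rises were in part set in advance. ZIC1 stood at 9.27 ± 0.17. The mesenchyme list had 9 of 13 genes up and 1 down (median 2.26, camera adjusted p = 0.00806, and adjusted p = 0.343 with an estimated correlation). Smooth muscle actin ACTA2 stood at 7.55 ± 0.20 and the surface protein THY1 at -5.15 ± 0.21. The extracellular matrix list had 16 of 23 genes up and 1 down (median 2.25, camera adjusted p = 0.00154, and adjusted p = 0.441 with an estimated correlation). LAMA4 stood at 5.59 ± 0.11 and tenascin TNC at 6.95 ± 0.30. Of the 17 p53 targets 12 rose and 1 fell (median 1.072, camera adjusted p = 0.0173, and adjusted p = 0.0669 with an estimated correlation). The G1/S list had 22 of 25 genes down and 1 up, or 23 down adjusted over the list alone (median -1.52, camera adjusted p = 5.11e-07), and the G2/M list 24 of 27 down and none up (median -1.59, camera adjusted p = 1.18e-06). MCM3 changed by -2.95 ± 0.09 and CCNB1, a mitotic cyclin gene, by -1.93 ± 0.07.

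Of the 13 protein genes of the mitochondrial genome 11 rose (median 1.24, camera adjusted p = 0.0256, and adjusted p = 0.484 with an estimated correlation). MT-CO1 stood at 1.65 ± 0.21 and MT-ND1 at 1.51 ± 0.21. Copies of these genes in the nuclear genome share their sequence, so the assignment of reads to them is uncertain. Nuclear genes of the mitochondrial ribosome had 56 of 74 members down and 3 up, or 58 down adjusted over the list alone (median -1.08, camera adjusted p = 9.58e-07, and adjusted p = 0.442 with an estimated correlation). MRPS27 stood at -1.32 ± 0.08. ATP synthase genes had 10 of 16 members down, or 8 adjusted over the list alone (median -0.68, camera adjusted p = 0.0405, and adjusted p = 0.657 with an estimated correlation). ATP5B stood at -1.12 ± 0.11, and 14 of these genes were down adjusted over the list alone when idebenone library 1 was left out. Glycolysis genes had 16 of 19 members down and 2 up (median -1.15, camera adjusted p = 0.000216, and adjusted p = 0.0855 with an estimated correlation). LDHA stood at -3.89 ± 0.09. Antioxidant genes had 12 of 21 members down and 2 up (median -0.54, camera adjusted p = 0.0173, and adjusted p = 0.395 with an estimated correlation). The glutathione reductase gene GSR stood at -1.73 ± 0.08 and catalase CAT at 1.00 ± 0.18. Ribosomal protein genes had 46 of 75 members down, or 43 adjusted over the list alone (median -0.87, camera adjusted p = 0.000216, and adjusted p = 0.657 with an estimated correlation). Once idebenone library 1 was left out all 75 fell. PPARGC1A was 4.60 ± 0.26 higher (adjusted p = 1.66e-10), CPT1A 2.31 ± 0.11 higher, and TFAM changed by -1.83 ± 0.19.

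In this comparison 11010 genes passed, 5709 up and 5301 down, and 23 of 46 lists were called. Median scaling moved the median of all genes by -0.129 and quantile normalization by -0.110, and no called list changed sign. The balance of directions turned: the share of changed genes that were higher went from 51.9% to 47.6% and 48.0% under these, and to 42.7% with length and GC trends removed. The ATP synthase call ended with length and GC trends removed (adjusted p = 0.183) while the median went from -0.68 to -0.66, within a range of adjusted p over such alternatives of 0.00374 to 0.183. The same fit added calls for mitochondrial biogenesis genes, with a median that went from -0.57 to -1.04 (adjusted p = 0.0386, range 0.0369 to 0.0828), and for replication-dependent histone genes, with one that went from 0.80 to 1.069 (adjusted p = 0.0346, range 0.0346 to 0.125). Leaving out idebenone library 1 added calls for complex I (median -0.33, adjusted p = 0.0206), complexes II and III (median -0.62, adjusted p = 0.0206) and complex IV (median -0.50, adjusted p = 0.0316), which had adjusted p = 0.471, 0.335 and 0.454 with an estimated correlation. Of the 46 lists, 11 were called in none of the 7 comparisons with all libraries and no trend removed: those of dopamine neurons, oligodendrocytes, neural crest, forebrain, mitochondrial biogenesis, mitochondrial dynamics, the citric acid cycle, hypoxia, heat shock, WNT targets and replication-dependent histones.

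Bezafibrate was compared with untreated NP to ask which genes its addition changed. ANGPTL4, a secreted inhibitor of lipoprotein lipase and a PPAR target, rose from -0.02 ± 0.32 to 6.36 ± 0.11, a change of 6.38 ± 0.35 (adjusted p = 1.13e-07), with 60 reads in the 3 NP libraries and 5536 in the 3 bezafibrate libraries. CPT1A rose from 5.49 ± 0.06 to 7.47 ± 0.11, by 1.98 ± 0.11 (adjusted p = 1.13e-07). SLC25A20, the carnitine carrier of the inner mitochondrial membrane, rose by 0.83 ± 0.10 (adjusted p = 0.00349), and CDCA7L, a nuclear protein, by 0.56 ± 0.08 (adjusted p = 0.0120). Each of the 4 was higher in the bezafibrate library than in the NP library of the same experiment in all 3 experiments.

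On GRCh38 ANGPTL4 lies on chromosome 19 from 8363289 to 8374373, CPT1A on chromosome 11 from 68754620 to 68844410, SLC25A20 on chromosome 3 from 48856931 to 48898993, and CDCA7L on chromosome 7 from 21900900 to 21946084. PDK4, the kinase that turns off pyruvate dehydrogenase and a PPAR target, stood at 1.68 ± 0.36 without passing (adjusted p = 0.54). The next largest moderated t values included those of the transcription factor KLF11 at 0.62 (adjusted p = 0.152) and MMD at 0.47 (adjusted p = 0.327), and among the lowest were the pyruvate carboxylase gene PC at -0.44, the glucose transporter gene SLC2A1 at -0.34 and BAIAP3 at -0.64, each with adjusted p = 1.00. PPARGC1A at 0.08, TFAM at 0.02, PPARA at -0.13 and the lipid droplet gene PLIN2 at 0.19 did not pass either.

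**Figure D3:**
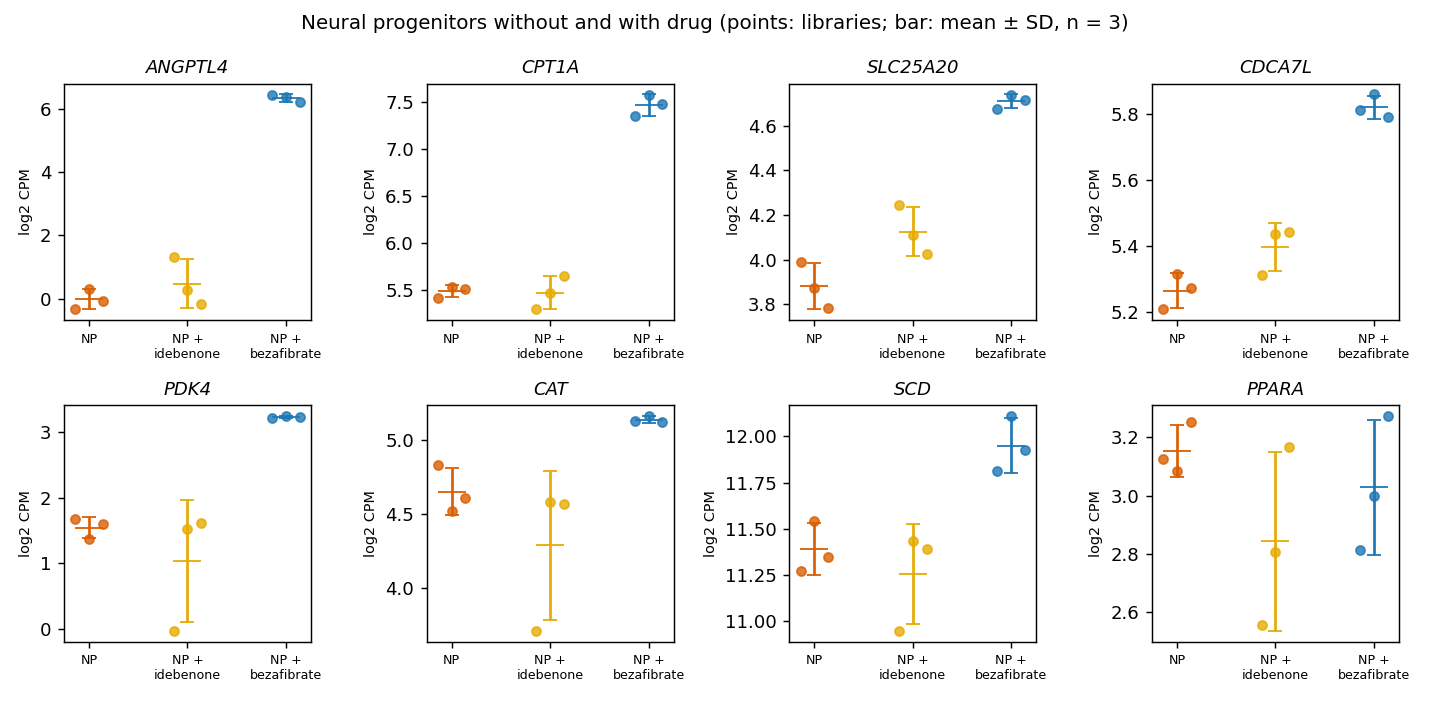
Log2 CPM of 8 genes (vertical axes) in NP, NP with idebenone and NP with bezafibrate (horizontal axes), with a point for each library and a bar for the mean ± SD (n = 3). ANGPTL4 lay at -0.02 in NP and 6.36 with bezafibrate, and CPT1A at 5.49 and 7.47.

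The list of PPAR targets and fatty acid oxidation genes was higher with bezafibrate (26 members, median 0.07, mean 0.50, camera adjusted p = 9.46e-18). Over all genes 3 members rose, and adjusted over the list alone 6 rose: CPT1A, SLC25A20, ANGPTL4, PDK4, and, chosen after their values were seen, the fatty acid oxidation genes HADHB at 0.32 and ETFDH at 0.28. In the fit without idebenone library 1, 6 rose over all genes and 10 adjusted over the list alone. The cholesterol synthesis list was higher (25 members, median 0.15, camera adjusted p = 1.08e-07), with 0 members passing over all genes. Only in the fit without idebenone library 1 did 12 of them pass adjusted over the list alone, among them the synthase gene HMGCS1 at 0.42 and the sterol sensor INSIG1 at 0.37. In that fit the list had adjusted p = 0.0997 with an estimated correlation, against 0.00282 with all libraries. The lipogenesis list was higher (10 members, median 0.16, camera adjusted p = 1.4e-09, and adjusted p = 0.0753 with an estimated correlation), with 2 members up adjusted over the list alone, the desaturase gene SCD at 0.56 and the elongase gene ELOVL6 at 0.39, and 5 when idebenone library 1 was left out. NRF2 targets had a median of 0.13 (camera adjusted p = 0.000871, and adjusted p = 0.069 with an estimated correlation). The neuron list had one of -0.13 (camera adjusted p = 0.0121, and adjusted p = 0.504 with an estimated correlation).

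Another 7 lists were called with small medians and with no member passing over all genes. The number of lists called for bezafibrate was 12 with all libraries, but 6 when NP library 1, NP library 3 or bezafibrate library 1 was left out. Mitochondrial genome genes stood at 0.18 (camera adjusted p = 0.00433, and adjusted p = 0.555 with an estimated correlation), stress response genes of the unfolded protein response at 0.08 (camera adjusted p = 0.04, and adjusted p = 0.555 with an estimated correlation), G1/S genes at 0.04 (camera adjusted p = 0.0121, and adjusted p = 0.0753 with an estimated correlation) and G2/M genes at 0.07 (camera adjusted p = 0.04, and adjusted p = 0.504 with an estimated correlation). Notch genes stood at -0.15 (camera adjusted p = 0.00782, and adjusted p = 0.069 with an estimated correlation), proneural genes at -0.12 (camera adjusted p = 0.0305, and adjusted p = 0.504 with an estimated correlation) and synapse genes at -0.09 (camera adjusted p = 0.0305, and adjusted p = 0.555 with an estimated correlation). With length and GC trends removed these 7 calls ended, with adjusted p between 0.086 and 0.25 and medians of 0.14, 0.07, 0.02, 0.05, -0.10, -0.09 and -0.06 in the same order. When idebenone library 1 was left out as well, 11 lists were called for bezafibrate. Among them were mitochondrial genome (adjusted p = 0.0329), unfolded protein response (adjusted p = 0.0489), Notch (adjusted p = 0.0329) and proneural genes (adjusted p = 0.0472), but not G1/S (adjusted p = 0.133), G2/M (adjusted p = 0.0509) or synapse genes (adjusted p = 0.16). Complex IV was called once that library alone was left out (median -0.11, adjusted p = 0.0149, and adjusted p = 0.64 with an estimated correlation).

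In all 4 genes passed with bezafibrate, 4 up and 0 down, of 243 with an unadjusted p under 0.05, and voom passed 6. The 243 lay below a share of 0.05 of the 14619 genes, about what no change at all would give. After idebenone library 1 was left out, 18 passed, all up: the first 4 were joined by PDK4 (adjusted p = 0.00165), the oxidation enzyme gene ECH1 at 0.70 (adjusted p = 0.000616), the lipid exporter gene ABCA1 at 0.69, KLF10 at 0.71, KLF11, MMD, ACADVL at 0.38, ACSL3 at 0.44, SLC7A8 at 0.74, PIPOX at 0.49, ACAA2 at 0.34, ELOVL6, SCD (adjusted p = 0.0315) and CAT at 0.49 (adjusted p = 0.0307). Those of these genes that the naming rule did not pick were chosen after their values were seen.

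Idebenone was compared with untreated NP in the same way. No gene passed: limma gave 0 genes with 1730 at an unadjusted p under 0.05, and voom gave 0 with 1204. Without idebenone library 1 limma again gave 0, with 421 unadjusted, and voom 0 with 548. Both of these lay below a share of 0.05 of the 14619 genes, about what no change at all would give. The largest moderated t values were those of PIGX, of GPI anchor synthesis, at 0.50 ± 0.14, HTATSF1, a splicing factor, at 0.25 ± 0.07, and LIF, a cytokine, at -0.61 ± 0.20, and the lowest adjusted p of any gene named was 0.307. The quinone reductase gene NQO1 stood at 0.47 ± 0.24, CPT1A at -0.02 ± 0.11 (adjusted p = 0.914), PPARGC1A at -0.21 ± 0.26 (adjusted p = 0.569) and MT-ND1 at -0.07.

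Camera called 10 lists for idebenone, none with a member passing, and each had adjusted p = 0.672 with an estimated correlation. The ribosomal protein list had a median of 0.60 (camera adjusted p = 5.51e-15), that of the mitochondrial ribosome 0.39 (camera adjusted p = 1.9e-09), that of complex I 0.57 (camera adjusted p = 3.42e-08), that of complexes II and III 0.36 (camera adjusted p = 0.00423), that of complex IV 0.51 (camera adjusted p = 0.00167) and that of the ATP synthase 0.55 (camera adjusted p = 2.74e-05). In complex I NDUFS6 stood at 1.10 ± 0.45, in complex IV COX4I1 at 0.80 ± 0.37, and in the ATP synthase ATP5D at 1.32 ± 0.56, against 0.26, 0.10 and 0.27 without idebenone library 1. Antioxidant genes had a median of 0.43 (camera adjusted p = 0.00169), PPAR targets and fatty acid oxidation genes 0.20 (camera adjusted p = 0.0029), unfolded protein response genes 0.20 (camera adjusted p = 0.0336) and extracellular matrix genes -0.51 (camera adjusted p = 0.00135).

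These lists moved with idebenone library 1. When that library was left out the medians were 0.02 for ribosomal protein genes, 0.01 for the mitochondrial ribosome, -0.02 for complex I, -0.01 for complexes II and III, -0.04 for complex IV, 0.01 for the ATP synthase, 0.08 for antioxidant genes and -0.05 for matrix genes, and none of these was called. With trends removed as well, complex IV alone was called, and downward (median -0.07, adjusted p = 0.0286, range 0.00167 to 0.396 over its alternatives). Leaving out that library brought the PPAR and fatty acid oxidation list from a median of 0.20 to 0.07, still called (camera adjusted p = 0.047, and adjusted p = 0.979 with an estimated correlation), within a range over its alternatives of 0.0029 to 0.263, and the unfolded protein response call ended (adjusted p = 0.538). Mitochondrial genome genes went from a median of -0.07 with all libraries, not called, to 0.19 without idebenone library 1, called at camera adjusted p = 0.047 and adjusted p = 0.979 with an estimated correlation. Over the fits with the block, the trends removed or that library left out their adjusted p ran from 0.0214 to 0.925, and with trends removed and all libraries kept the median was -0.49. Mitochondrial genome genes took 4.15% of the reads in idebenone library 1, and 5.94 and 6.07% in the other two.

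**Figure D4:**
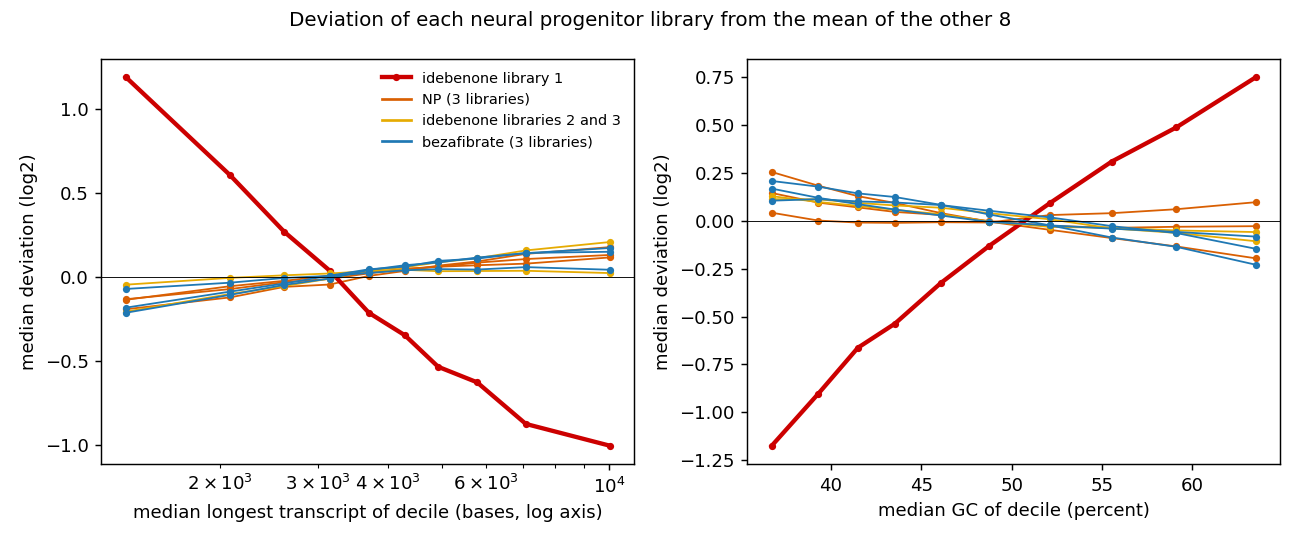
Median deviation (log2, vertical axes) of each of the 9 neural progenitor libraries from the mean of the other 8, over deciles of genes by longest transcript (bases, log axis) and by GC content (percent), with a line for each library and idebenone library 1 in red. Idebenone library 1 deviated with an SD over genes of 1.06 and kept one of 0.715 once length and GC trends were taken out. The others kept at most 0.121, a value computed with library 1 out of their reference, unlike the lines drawn.

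The drugs were then set against each other, which tests their difference directly. The compounds differ in kind and in dose, 0.5 microM against 50 nM. CPT1A was lower with idebenone than with bezafibrate, at -2.00 ± 0.11 (adjusted p = 1.81e-07), and so was ANGPTL4, at -5.88 ± 0.35 (adjusted p = 3.61e-07), both in all 3 experiments. PDK4 stood at -2.19 (adjusted p = 0.0859), KLF11 at -0.68 (adjusted p = 0.0859) and SLC25A20 at -0.58 (adjusted p = 0.0987). In total 2 genes passed, 0 up and 2 down, of 2068 unadjusted, and voom passed 5. Without idebenone library 1, 13 passed: PDK4 at -1.66 (adjusted p = 0.0136), ABCA1 at -0.75, SLC25A20 at -0.64, ACADVL at -0.44, KLF11 at -0.58, ECH1 at -0.57, MMD at -0.43, CAT at -0.56, KLF10 at -0.59, CDCA7L at -0.38, CPT1A and ANGPTL4 were lower with idebenone and ALDH6A1, of valine breakdown, was 0.39 higher, and those outside the naming rule were chosen after their values were seen. Without idebenone library 2 the count was 2 and without idebenone library 3 it was 4538, and both fits kept idebenone library 1, which stood apart. Against NP, 0 genes passed without idebenone library 3.

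Between the drugs 10 lists were called, none with a call that held with an estimated correlation. The complexes of the respiratory chain, both ribosomes and the antioxidant genes were higher and the matrix genes lower with idebenone, all moving with idebenone library 1. Ribosomal protein genes had a median of 0.60 (camera adjusted p = 8.41e-14, and adjusted p = 0.688 with an estimated correlation), and 0.02 without that library (adjusted p = 0.393). Cholesterol genes stood at -0.22 (camera adjusted p = 0.0179, and adjusted p = 0.64 with an estimated correlation) and lipogenesis genes at -0.42 (camera adjusted p = 1.61e-05, and adjusted p = 0.64 with an estimated correlation), with 8 members of each down adjusted over the list alone. Without idebenone library 1 their medians were -0.16 and -0.21, both were still called, with 5 lipogenesis genes down adjusted over the list alone, and with an estimated correlation they had adjusted p = 0.0168 and 0.027. That fit also called the PPAR and fatty acid oxidation list, 5 of whose members fell (median -0.04, adjusted p = 1.67e-09, and adjusted p = 0.0168 with an estimated correlation). It called 6 more lists, none of which held with an estimated correlation: pluripotency (median 0.23, adjusted p = 0.453 with an estimated correlation), neuron (0.13, adjusted p = 0.476), synapse (0.11, adjusted p = 0.476), WNT targets (0.10, adjusted p = 0.476), hypoxia (-0.11, adjusted p = 0.374) and G2/M (-0.06, adjusted p = 0.453). With trends removed and all libraries kept, G2/M genes were called at -0.14 (adjusted p = 0.00513, range 0.00513 to 0.105) and mitochondrial genome genes at -0.67 (adjusted p = 0.000551, range 0.000551 to 0.946), but without that library the latter stood at -0.03. SCD stood at -0.69.

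Across 14619 genes the idebenone and bezafibrate effects correlated with r = 0.0769 and a covariance of 0.00521, and 50.3% had the same sign. Both effects use the same 3 NP libraries, so part of any excess over 0 may come from these shared controls, and 3 libraries cannot be split between the drugs. In 100 simulations of unchanged groups sharing 3 controls the correlation was 0.501, the covariance 0.0333 and the share of equal signs 66.6%. Without idebenone library 1 the correlation was 0.460 against 0.448 in simulations, the covariance 0.0114 against 0.0118, and equal signs 69.8% against 64.8%. Genes are not independent replicates. In neither fit was the covariance larger than in these simulations, while without idebenone library 1 the share of equal signs was. The simulated noise came from the residual spread of all groups, not from the NP libraries alone, and idebenone library 1 widens it. The simulations therefore cannot decide whether the drugs share an effect.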

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

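The tests of length and GC content and of a shared idebenone response for idebenone library 1 were chosen only after that library's values had been seen. Each result in this first paragraph was picked because the idebenone and bezafibrate groups differed in a direct limma or camera test of the difference. Given as idebenone minus bezafibrate, CPT1A stood at -2.00 and ANGPTL4 at -5.88, lower in all 3 same-numbered pairs. The list medians were 0.60 for complex I (camera adjusted p = 2.64e-08), 0.40 for complexes II and III (0.0179), 0.63 for complex IV (0.000299), 0.49 for the ATP synthase (0.000187), 0.40 for the mitochondrial ribosome (2.64e-08) and 0.60 for ribosomal proteins (8.41e-14). The others were -0.22 for cholesterol synthesis (0.0179), -0.42 for lipogenesis (1.61e-05), 0.38 for antioxidant genes (0.027) and -0.555 for the extracellular matrix (0.006). With an estimated correlation none of these lists passed, their adjusted p lying between 0.64 and 0.781. Leaving out idebenone library 1 brought the medians to 0.04, 0.02, 0.05, 0.02, 0.02 and 0.02 for the first 6 in that order, and to -0.16, -0.21, 0.01 and -0.04 for the others.

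Idebenone library 1 stood apart from the other 8 neural progenitor libraries, and a candidate explanation is a bias with transcript length and GC content in that library, since splines on both explained 54.1% of the variance of its deviations. By that share the cause stays open: the same splines explained up to 57.5% in another library, bezafibrate library 3, or up to 42.0% with library 1 out of the reference. In size, however, the trend was larger in library 1. Its median deviation went from 1.19 in the shortest decile of genes to -1.01 in the longest. Bezafibrate library 3 went from -0.21 to 0.17, with library 1 in its reference. The SD they left was 0.715 in library 1, against at most 0.121 in the others with library 1 out of their reference. RNA or a label from another stage of the series could also set it apart, but 82.1% of the 1469 genes it raised by over 1 exceeded all 17 other libraries, which argues against it. A response to idebenone shared by the 3 cultures, the biological explanation here, has against it that ribosomal protein genes in idebenone libraries 2 and 3 had a median change of 0.0186, within the SD of 0.0219 between NP libraries. A response of that one culture, or its RNA quality, was not tested.

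The cell cycle lists were lower in NP than in eNP, and without idebenone library 1 a count of 1087 genes separated these stages. A trend with length and GC content could give such small changes, but with it removed both lists kept at least 69.1% of their median, which argues against the trend as the whole cause of their fall. For the count that stays open: 1090 genes passed with the trend removed, 100.3% of the count before, with 476 up and 614 down against 538 and 549, but how many were the same genes was not tested. The stage itself, the biological explanation, cannot be told apart from anything else that differed between the eNP and NP cultures.

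Ribosomal protein and mitochondrial ribosome genes were lower in eNP than in NSC. A trend with length and GC content might lower such short genes, but with it removed and idebenone library 1 left out their medians were -1.45 and -0.48, which argues against it as the whole cause. Reads shared with pseudogenes might also do so, but the 21 ribosomal protein genes with at most 3 named pseudogenes had a median of -1.44, against -1.81 for the other 54. Both lists lost their call with an estimated correlation. The stage itself stays open, since no value here parts it from the way each stage's cultures were grown.

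With length and GC trends removed the PPAR and fatty acid oxidation list kept its bezafibrate call with adjusted p = 1.51e-14. The 6 libraries of a comparison can be split 3 against 3 in 10 ways, so no share of splits under 0.1 can arise. The true grouping alone, 1 of 10 splits, gave its count in 6 comparisons: 10211 for NSC against hiPSC, 7420 for eNP against NSC, 1 for NP against eNP, 11010 for NP against hiPSC, 4 for bezafibrate against NP and 2 for idebenone against bezafibrate, with 0 as the highest other count. For idebenone against NP all 10 splits gave 0. Every other split mixes the groups, and those that part all 3 same-numbered pairs, as the true grouping does, gave 0 as well.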

How the results depend on the processing

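Leaving out idebenone library 1 as a setting of its own, voom, and removal of length and GC trends were chosen after seeing the data, as were their combinations. The counts for NSC against hiPSC, eNP against NSC and NP against hiPSC stayed within 1.5 times under every setting. The filter at log2 CPM above 0 removed no gene, so a run without it decides nothing. Where a value moved, the cause was not tested.

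For NP against eNP the count of 1 became 0 with log2(CPM + 1), quantile normalization, robust variances, the replicate block, only the 2 groups compared, and voom, and 2 with median scaling and with no variance trend. It was 4591 with library weights, 32 with trends removed, 1090 with trends removed and idebenone library 1 left out, 1609 with the replicate block and that library left out, 1309 with all of these, and 2174 with voom without that library. For idebenone against NP the count was 4115 with library weights. The bezafibrate count of 4 became 257 with library weights, 7 with only the 2 groups, 10 with trends removed, 22 with trends removed and the library left out, 22 with the replicate block and the library left out, 39 with all of these, and 35 with voom without that library. The count of 2 between the drugs became 6 with log2(CPM + 5), 4 with quantile normalization, 3367 with library weights, 0 with only the 2 groups, 13 with trends removed, 20 with trends removed and the library left out, 13 with the replicate block and the library left out, 18 with all of these, 5 with voom, and 20 with voom without that library. The library weights did not converge, with 0.00272 for idebenone library 1 and 21.1 for idebenone library 2, and the counts they gave conflict with those of leaving that library out.

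Called lists with an estimated correlation numbered 1 for eNP against NSC, 1 for NP against eNP, 10 for NP against hiPSC, 0 for idebenone, 2 for bezafibrate and 0 between the drugs. With idebenone library 1 also left out they numbered 3 for NSC against hiPSC, 0, 1, 3, 0, 1 and 3 for the others in that order. With trends removed 5 lists were called for bezafibrate, and with the library also left out 1 for idebenone, complex IV.

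With each library of the compared groups, or idebenone library 1, left out in turn the counts ranged from 9477 to 12417 for NSC against hiPSC, 6310 to 10671 for eNP against NSC, 0 to 1087 for NP against eNP, 10428 to 12894 for NP against hiPSC, 0 to 0 for idebenone, 3 to 18 for bezafibrate, and 2 to 4538 between the drugs. Called lists ranged from 15 to 16, 18 to 20, 5 to 6, 23 to 26, 2 to 11, 6 to 13 and 9 to 10. The correlation of the drug effects ran from 0.0481 to 0.460 with an NP library or idebenone library 1 left out, and no other library was left out for it. A group left with 2 libraries shares the spread of all groups.

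Of 16453 values of named genes under other settings 15823 kept direction and side of the threshold, 26 lost the call, 586 gained it and 18 turned. With trends removed, trends removed and idebenone library 1 left out, and both with the replicate block, NES in eNP against NSC was -0.57, -0.57 and -0.57, PPARA -0.56, -0.56 and -0.56, and MKI67 -0.64, -0.64 and -0.64. In NP against hiPSC PPARA was -0.45, -0.44 and -0.44 and MKI67 -0.93, -0.92 and -0.92, and in NSC against hiPSC MKI67 was -0.17 with the library left out, block or not. With library weights MT-ND1 for idebenone was 0.23. The replicate block on its own changed the NP against eNP count and ended the HOX call in eNP against NSC, added a call for PLIN2 there (0.34), and changed no other call given in the text. Of 18 libraries 10 matched best a library of the same number, a count for which no chance level was computed.

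In the simulated libraries, planted changes of log2 0.5 were found in 8.96% of genes for idebenone and 4.48% for bezafibrate with all libraries. Without idebenone library 1 they were found in 31.3% and 52.2%, so a change of that size which did not pass is not shown to be absent.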

Other observations

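The genes in this part were chosen after their values were seen. No list of class II antigen presentation genes was fixed or tested, and these 5 were picked because they were higher in eNP than in NSC. CD74, the invariant chain, rose by 4.88 ± 0.31 (adjusted p = 8.67e-09, limma), from 131 to 6046 reads over 3 libraries each, and HLA-DRA by 4.63 ± 0.22 (adjusted p = 3.36e-10), from 114 to 5532 reads. CIITA, the transcriptional activator of these genes, rose by 4.63 ± 0.29 (adjusted p = 8.02e-09), from 6 to 430 reads, and HLA-DOA by 4.62 ± 0.31. In hiPSC, however, HLA-DOA lay higher than at any later stage: it changed by -7.72 ± 0.31 from hiPSC to NSC and was 5.30 in hiPSC against 2.19 in eNP. CD74 also changed by -3.65 ± 0.31 from hiPSC to NSC. HLA-DRB1 rose by 5.62 ± 0.52, though its paralogs share reads with it. From eNP to NP no call was made, with CD74 at 0.06 and HLA-DRA at 0.08.

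A few marker lists had fewer than 5 measured members and were not tested. In them FOXA1, of endoderm, had a mean log2 CPM of -3.27 in hiPSC, -1.76 in NSC, 2.01 in eNP and 2.04 in NP. KDR, a receptor of endothelial cells, stood at 6.44, 1.35, 4.75 and 5.31, and TEK, another, at 5.45, 0.98, 1.90 and 2.38. In the same list AIF1 stood at 2.38, -3.27, -3.17 and -3.27 and CLDN5 at -1.60, 0.78, 1.43 and 1.88, so its members did not move together. Of the muscle genes ACTC1 stood at 4.15, -0.83, -1.91 and -2.27 and TNNT2 at 3.38, -2.51, -3.27 and -3.27. The ventral homeobox gene NKX6-1 stood at -2.18, 1.66, 3.63 and 4.01, and the hedgehog receptor PTCH1 at 4.73, 7.93, 7.11 and 6.88. AFP, of endoderm and yolk sac, stood at 2.24, 1.63, 0.36 and 0.80.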
